A study of Rattus norvegicus with 2 samples.

How the data were processed

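RNA from cultured skeletal muscle stem cells (MDSC) of male obese Zucker fa/fa rats was measured on the Affymetrix Rat Gene 1.0 ST array, a 1-colour array that summarises many short probes per transcript into 1 probe set. The labels give 2 samples, 1 of early diabetes and 1 of late diabetes. Per the labels' protocols, the cells were grown in Dulbecco's medium with 20% fetal bovine serum and 5.6 mM or 22 mM glucose, RNA was taken from single wells with a column kit, and the arrays were run in a university laboratory by the manufacturer's protocol. The labels give the same 2 glucose levels for both samples, give no age of the rats, and do not say how many rats or wells lie behind each array.

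The authors deposited normalized intensities on a linear scale, 1 value per probe set and array, in 2 tables, 1 with gene symbols. Their background correction, summary and normalization methods and software are not given in the sources used here, and neither is the genome build behind the annotation. The 2 tables held identical values for all 29214 probe sets. All values equalled a power of 2 of a number with 6 decimals (within a relative 1e-08), so the deposited intensities look like antilogs of log2 values. Because a normalization sets the arrays to a common scale, a difference in total RNA per cell could not be seen.

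The design fixed before the data were examined worked on log2 values. The deposited intensities were linear, so log2 was taken first, with no pseudocount. Of the 29214 probe sets, 20164 named 1 gene, 328 named several, 8696 named none, and 26 carried a symbol damaged by a spreadsheet. Only probe sets naming 1 gene were used, and the probe sets of a gene were averaged, which gave 18489 genes, 988 of them with several probe sets. Symbols were checked against a RefSeq gene table of the GRCr8 rat assembly: 14303 were current, 2779 were an older name of 1 gene and 1407 had no match. Names are printed as the deposited table gives them, and no coordinates are given, since the builds could differ. Genes whose symbol is not in the annotated table, such as Acta2, are not analysed here.

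A gene was compared when the brighter of its 2 values reached the median of all gene values over both arrays (log2 8.03, an intensity of 261), which kept 9738 genes. The file carries no detection calls. As a background level, chosen after the data were seen, the 95th percentile of 1199 olfactory receptor genes was taken (log2 6.81, an intensity of 112). Most of these genes were assumed to be silent in the cells, which was not tested. Where the dimmer value lay below it, a fold is given as "at least", from the brighter value to that level. No fold is given when both values lie below it. Array number limits the precision: with 1 array per group there is no estimate of the spread between cultures or animals, and no test of any gene was made. The spread between 2 probe sets of one gene is given instead and covers probe error only.

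Genes named in the text follow a rule fixed before the data were examined. They are the 12 with the largest difference in each direction among compared genes with a proper symbol, the 2 highest and 2 lowest compared members of each fixed list if at least 1.5-fold apart, and 16 chosen genes whatever their values, 15 of which were found. Not every gene the rule allows is printed, some items are not reported here, and exceptions are marked where they stand. The 30 gene lists and 8 cell type marker sets were fixed at the same time, and 7 of their 999 measured genes sit in more than 1. For each list with at least 5 compared members, the median late minus early difference was set against the medians of 10000 random lists of the same size, drawn from the compared genes in 20 bins of mean log2 value. A list is said to lie outside its random range when its percentile is under 2.5 or over 97.5.

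Alternatives were other fold thresholds (1.5-fold and 3-fold), no filter or a 75th percentile filter on dim genes, quantile normalization, median centring, removal of a lowess trend of the difference on mean brightness (span 0.3), the brightest probe set in place of the mean, a pseudocount of 16, means in place of medians and random lists not matched on brightness. The background filter and the removal of genes held by several lists were added after the data were seen. The calculations were tested on simulated data with 9459 compared genes and a difference SD of 0.2: all 100 genes changed by 1.5 and all 100 changed by 3 on the log2 scale were recovered with 0 unchanged genes called. With so small an SD this outcome was nearly certain. The differences between the real arrays had an SD of 0.64, and spread between cultures was not simulated. The simulation therefore checks the calculations and gives no rate of false calls in the real arrays. In the same data, 14 of 200 random lists (7%) lay outside their range, and all 50 lists of 25 genes shifted by 0.3 lay above it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.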

Results

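Gene expression was measured in cultured skeletal muscle stem cells, called muscle-derived stem cells or MDSC below, from male obese Zucker fa/fa rats. These rats carry a mutation of the leptin receptor and become obese and insulin resistant. The series comes from work on implanting such cells in rats with erectile dysfunction, and its 2 samples set cells labelled early diabetes against cells labelled late diabetes. Each sample was 1 Affymetrix Rat Gene 1.0 ST array, so there were no replicates. No p-value, standard error or SD could be given for any gene, and all statements describe these 2 arrays. The 2 arrays held 29214 probe sets with a median normalized intensity of 187 in the early array and 183 in the late array. After probe sets were joined by gene there were 18489 genes, of which 9738 were bright enough in at least 1 array to be compared.

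The question put to the data was which genes differed between MDSC of early and of late diabetes. Of the fixed gene lists, those of cytokine genes (median difference 1.58 on the log2 scale) and cell cycle genes (1.30) were the highest in the late array. Those of cholesterol synthesis (-1.02), skeletal muscle contractile (-0.56) and bone and cartilage genes (-0.52) were the lowest among lists with at least 5 compared members. These medians are over compared genes. Over all measured members, dim ones included, the cytokine list stood at 0.60, below the cell cycle list. On that basis the unfolded protein list lay lower than the muscle (-0.21) and the bone and cartilage list (-0.26). The smooth muscle (-0.26), collagen (-0.22) and senescence (-0.22) lists then also lay lower than the skeletal muscle list. Of the 9738 genes compared, 569 were at least 2-fold higher and 303 at least 2-fold lower in the late array, so 8.95% of the genes were at least 2-fold apart. At 4-fold the counts were 123 higher and 71 lower, and at 16-fold 11 higher and 11 lower. These counts use measured differences, also where the dimmer value lay below the background level. Some genes counted at 16-fold are therefore not shown to be that far apart. Against the background level Prl7a3 was at least 8.93-fold higher and Omd at least 4.26-fold lower. The arrays correlated with Pearson's r = 0.89 and Spearman's rho = 0.89 across the compared genes, which are not independent replicates, and 81.4% of the genes lay within 1.5-fold. The only repeated measurement within these arrays was that of genes covered by 2 probe sets. Over 421 genes with 2 probe sets that each reached the brightness floor, the late minus early differences of the 2 correlated with r = 0.78. Their SD within a gene was 0.22 on the log2 scale. Over all 760 genes with 2 probe sets, dim ones included, r was 0.61 and the SD 0.30. Of the 25 genes among the 421 with at least 1 probe set 2-fold apart, 22 had both probe sets in the same direction. In 20 of them both were also at least 1.5-fold apart. This spread covers probe error, not the variation between cultures or animals.

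**Figure D1:**
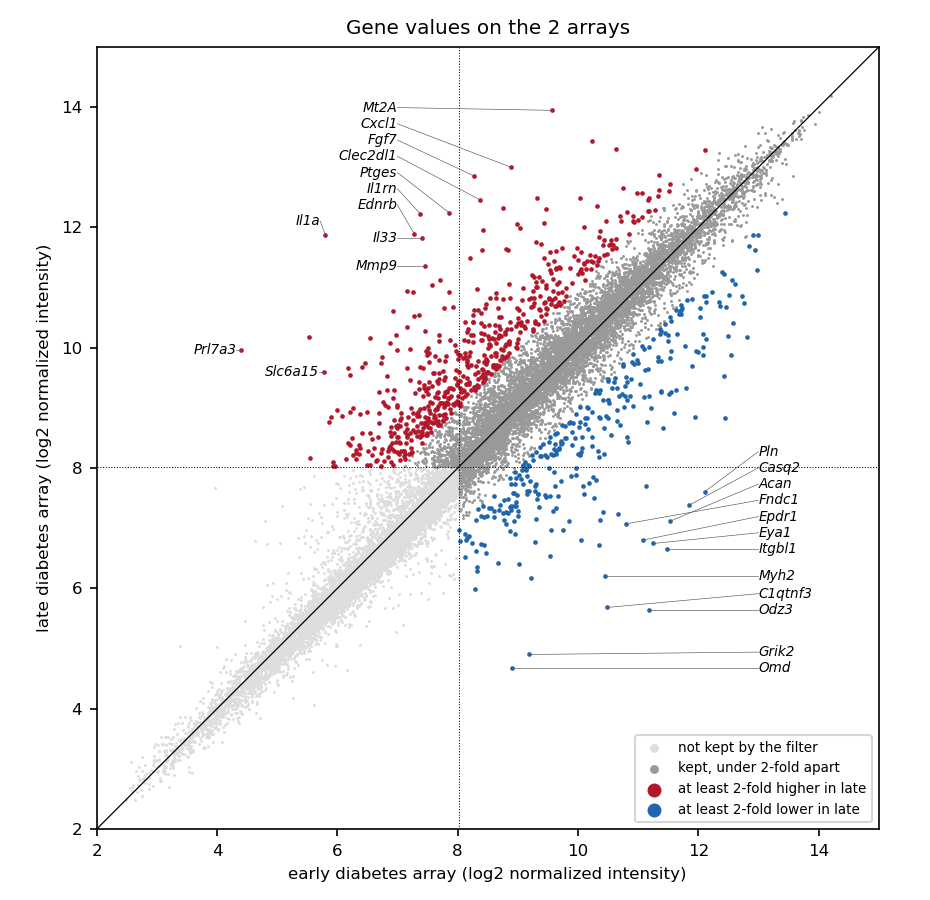
Log2 normalized intensity of each gene in the late diabetes array (vertical axis) against the early diabetes array (horizontal axis), 1 point per gene, with the line of equal values and dotted lines at the brightness floor of 8.03. Red points are the 569 genes at least 2-fold higher and blue points the 303 genes at least 2-fold lower in the late array, and the 12 genes with the largest measured difference in each direction are named, passing over placeholder symbols.

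The largest measured difference upward was that of Il1a, which encodes the cytokine interleukin-1 alpha. Its log2 intensity was 5.80 in the early array and 11.88 in the late array. The early value of Il1a lay below the level that 95% of olfactory receptor genes stayed under (log2 6.81), which served as a background, and against that level Il1a was at least 33.6-fold higher. Il1rn, the interleukin-1 receptor antagonist, was 28.7-fold higher (7.38 to 12.22), and Il33, another interleukin-1 family member, was 21.4-fold higher (7.41 to 11.83). Fgf7, a growth factor that acts on epithelial cells, was 24.1-fold higher and reached log2 12.86. Ptges, which makes prostaglandin E2, was 20.9-fold higher, and Cxcl1, a neutrophil chemokine, was 17.2-fold higher. Ednrb, the endothelin B receptor, was 24.6-fold higher (7.28 to 11.90). Mt2A, a metal-binding metallothionein, was 20.8-fold higher and at log2 13.95 among the brightest genes of the late array. Mmp9, a matrix-degrading gelatinase, was higher by 3.91 on the log2 scale. Placeholder symbols passed over, the other genes of the 12 with the largest measured difference were Clec2dl1, a C-type lectin family gene (16.9-fold), and Prl7a3 and Slc6a15. For the prolactin family gene Prl7a3 and the amino acid transporter gene Slc6a15, the early values lay below the background level. Against that level they were at least 8.93-fold and 6.95-fold higher, so their place among the 12 rests on values below background.

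The largest measured difference downward was that of Odz3, now called Tenm3, which encodes the transmembrane protein teneurin-3. It was at log2 11.18 in the early array and 5.64 in the late array, at least 20.7-fold lower against the background level. Its first place rests on that dim late value, since against the background level Itgbl1 was at least 25.5-fold lower and Pln, above it in both arrays, 22.6-fold lower. Pln encodes phospholamban, a regulator of the calcium pump of the sarcoplasmic reticulum, and was at 12.11 and 7.61. Casq2, a calsequestrin that stores calcium there, was 22.0-fold lower (11.84 to 7.38), and Myh2, a fast myosin heavy chain, was at least 12.5-fold lower. Eya1, a transcription cofactor of muscle development, was at least 21.8-fold lower. Acan, the cartilage proteoglycan aggrecan, was 21.4-fold lower (11.54 to 7.12), and Omd, the bone matrix proteoglycan osteomodulin, was at least 4.26-fold lower. The remaining genes of the 12 with the largest measured difference downward were C1qtnf3 (at least 12.8-fold lower), Epdr1 (at least 19.2-fold), the glutamate receptor gene Grik2 (at least 5.18-fold) and Fndc1 (13.2-fold). For Omd and Grik2, too, a place among the 12 rests on late values below background. Myh2 lies in a family of closely similar myosin genes, whose probe sets can share signal.

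Lists of genes fixed before the data were examined were compared with random lists of the same size and brightness. Of 31 lists or cell type sets with at least 5 compared members, 8 had a median difference above the central 95% of 10000 random lists and 11 below it, where 1.55 would lie outside by chance if genes were independent. Genes of one pathway vary together, so real lists spread more than random ones even without a group difference. The placement therefore describes these 2 arrays and is not a test.

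**Figure D2:**
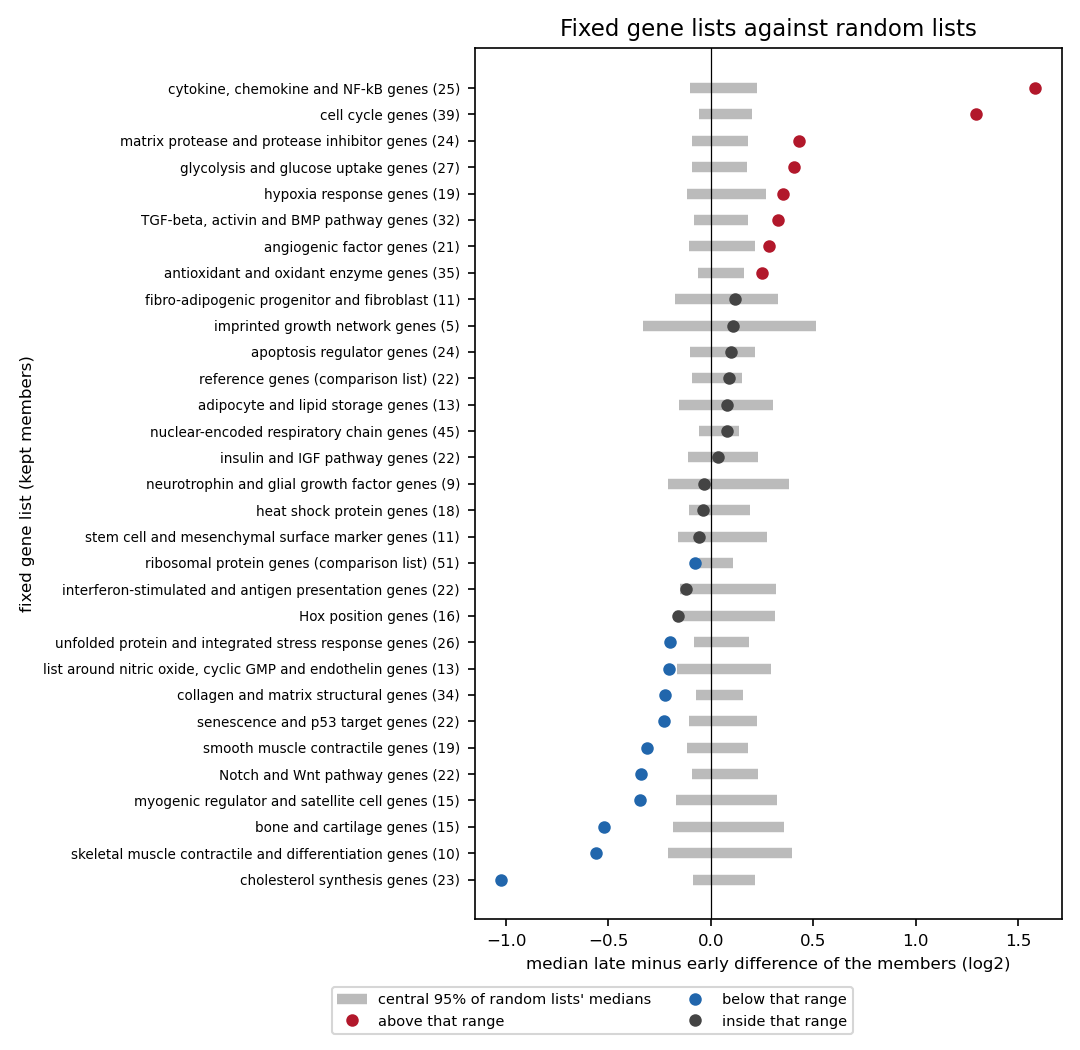
Median late minus early difference (log2, horizontal axis) of each fixed list with at least 5 compared members (vertical axis, number of compared members in brackets), with grey bars for the central 95% of the medians of 10000 random lists of matched brightness. Cytokine genes (1.58) and cell cycle genes (1.30) lie farthest above their bars, and cholesterol synthesis genes (-1.02) farthest below.

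Cell cycle genes were higher in the late array without exception among those compared. All 39 compared members had the higher value there, 32 of them by at least 2-fold, and the list's median difference was 1.30 on the log2 scale against a random range of -0.06 to 0.20. Ccne2, a cyclin of the entry into DNA synthesis, was 4.27-fold higher, and Dlgap5, a mitotic spindle gene, was 4.09-fold higher. Mki67, which encodes the proliferation marker Ki-67, was 2.21-fold higher (10.34 to 11.49). The list of senescence and p53 target genes had a median of -0.23, below its random range of -0.11 to 0.22. Of its 22 compared members, 4 were at least 2-fold lower and 0 at least 2-fold higher. The growth arrest gene Gadd45a was 3.18-fold lower, and Cdkn2b, an inhibitor of the cell cycle kinases Cdk4 and Cdk6, was 2.86-fold lower. Lmnb1, a nuclear lamina gene, was 1.81-fold higher. The inhibitor genes Cdkn1a (12.05 to 12.32) and Cdkn2a (8.79 to 8.94) differed by less than 1.5-fold.

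The cytokine, chemokine and NF-kB genes had a median of 1.58 against a random range of -0.10 to 0.23, the largest of the lists over compared genes. With no filter on dim genes the median of all 45 measured members was 0.60, and with the background filter it was 0.97, both above their random ranges but smaller than for cell cycle genes. Of 25 compared members, 17 were at least 2-fold higher in the late array, 2 were at least 2-fold lower and 6 were within 2-fold. Il1a and Il1rn led the higher members. The 2 lower members were the interferon-induced chemokine Cxcl10 (4.99-fold lower) and Cxcl12, a chemokine for stem and blood cells (2.94-fold lower). The interferon-stimulated and antigen presentation genes went both ways. Of 22 compared members, 4 were at least 2-fold higher and 5 at least 2-fold lower, and the median of -0.12 lay inside the random range as reported. Under 7 of 10 alternatives it lay below the range, from -0.12 against unmatched random lists to -1.497 over the 6 members kept by the 75th percentile filter. Oasl, an antiviral gene, was 5.65-fold lower and Ifit1 4.59-fold lower, while Usp18, which removes the interferon-induced protein Isg15 from its targets, was at least 4.89-fold higher and Psmb8, an immunoproteasome gene, 2.87-fold higher. The 2 probe sets of Ifit1 gave differences of -3.46 and -0.93. Of 20 measured white blood cell markers, 2 were bright enough to be compared, Cd68 (at least 2.49-fold higher) and Cd14 (1.69-fold higher). The median difference of all 20 markers was -0.025, and the pan-leukocyte gene Ptprc, chosen after its values were seen, was at log2 5.84 in both arrays, below the background level.

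Of 41 measured skeletal muscle contractile and differentiation genes, 10 were bright enough to be compared. In the late array 7 of these had the lower value and 3 the higher, and 4 were at least 2-fold lower and 0 at least 2-fold higher. Their median was -0.56 against a random range of -0.21 to 0.40. The size of this median depends on the filter. For the skeletal muscle contractile and differentiation genes it was -0.21 over all 41 measured members, -0.27 with the background filter and -1.98 over the 6 members kept by the 75th percentile filter, each below its range. Casq2 and Myh2 were the lowest members, and Xirp1, an actin-binding muscle gene, was 1.54-fold higher. Among 15 compared myogenic regulator and satellite cell genes, 5 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.34 against a random range of -0.17 to 0.32. With the 75th percentile filter the median was -0.21, inside its range. It was -0.20 with no filter and -0.18 with the brightest probe set, both below their ranges, and the mean was -0.76. Eya1 and the homeobox gene Meox2 (at least 9.42-fold lower) were the lowest, while Sdc4, a surface proteoglycan, was 1.84-fold higher and the intermediate filament gene Des 1.58-fold higher. The transcription factor genes that mark satellite cells and myoblasts were dim in both arrays. Pax7 was at log2 7.35 in the early and 7.38 in the late array, and Myod1 at 6.85 and 6.65, all under the floor of 8.03 for comparison. Mstn, which encodes the muscle growth inhibitor myostatin, was at 5.79 and 6.41, below the background level in both.

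Smooth muscle contractile genes had a median of -0.31, below the random range of -0.11 to 0.18, while their mean of -0.12 lay inside the range for means. None of the 19 compared members was 2-fold lower, and 14 had the lower value in the late array. Actg2, an enteric smooth muscle actin, and Mylk, the kinase of the myosin light chain, were each 1.95-fold lower. Against this direction, Myocd, a coactivator that drives smooth muscle genes, was 2.18-fold higher and the small heat shock gene Hspb7 was 2.47-fold higher. Acta2 was not analysed here. In the list built around nitric oxide, cyclic GMP and endothelin genes, 3 of 13 compared members were at least 2-fold higher and 4 at least 2-fold lower. Their median of -0.20 lay below the random range of -0.17 to 0.29, but the mean (-0.023) lay inside, as did the median with no filter (-0.16). The natriuretic peptide clearance receptor gene Npr3 was at least 11.6-fold lower and Prkg1, the cyclic GMP-dependent kinase, was 2.63-fold lower, while Ednrb was 24.6-fold higher and the guanylate cyclase subunit gene Gucy1a2 at least 2.33-fold higher. The nitric oxide synthase genes Nos1 (7.04 and 6.88), Nos2 (7.60 and 7.51) and Nos3 (7.74 and 7.37) were under the floor in both arrays.

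Collagen and structural matrix genes had a median of -0.22 against a random range of -0.07 to 0.16, and 25 of the 34 compared members had the lower value in the late array. Large differences were nearly balanced, with 4 members at least 2-fold lower and 3 at least 2-fold higher. Ogn, a small leucine-rich proteoglycan, was 4.03-fold lower and the fibrillar collagen gene Col11a1 3.95-fold lower. Thbs2, a matricellular thrombospondin, was 4.14-fold higher and Col15a1 3.33-fold higher. The bone and cartilage genes had a median of -0.52 against a random range of -0.18 to 0.36. Over all 23 measured members it was -0.26, and -0.26 with the background filter, both below their ranges. Of 15 compared members, 5 were at least 2-fold lower, led by Acan and Omd, and 2 were at least 2-fold higher, Msx2, a homeobox gene (5.25-fold), and Tnfrsf11b, the decoy receptor osteoprotegerin (2.13-fold). Matrix protease and protease inhibitor genes had a median of 0.43 against a random range of -0.09 to 0.18. Of 24 compared members, 6 were at least 2-fold higher, led by Mmp9 and Plau, the urokinase gene (at least 7.71-fold). One, the procollagen protease gene Adamts2, was at least 2-fold lower (2.16-fold).

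**Figure D3:**
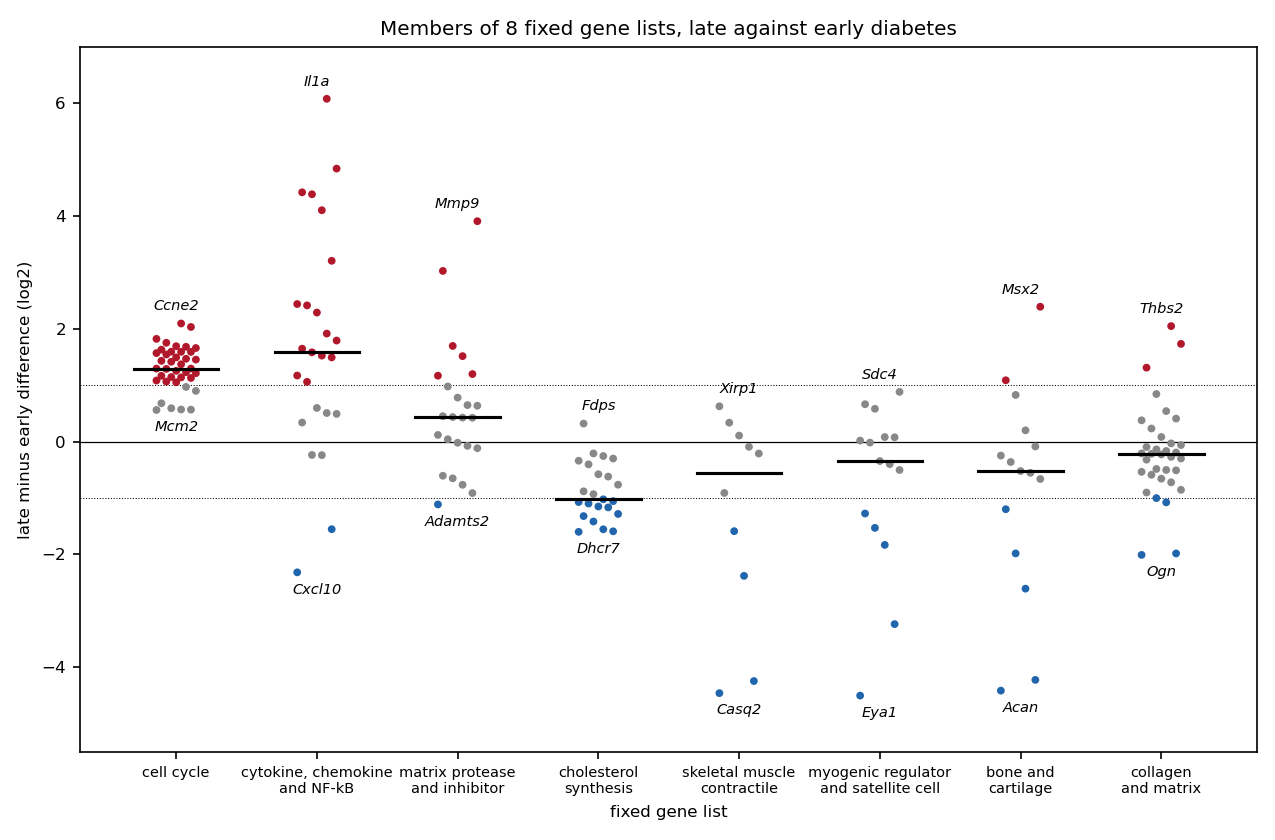
Late minus early difference (log2, vertical axis) of each compared member of 8 fixed lists (horizontal axis), 1 point per gene, with a black bar at the median and dotted lines at 2-fold. Red and blue points are at least 2-fold higher or lower in the late array. All cell cycle genes lie above 0, and the lowest muscle and cartilage genes lie below -4.

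Cholesterol synthesis genes had a median of -1.02 against a random range of -0.09 to 0.21, the lowest of the lists over compared genes. With no filter it was -0.98. Of 23 compared members, 22 had the lower value in the late array, 12 of them by at least 2-fold. Dhcr7, an enzyme of the last steps of the pathway, was 3.03-fold lower, and Insig1, a sterol-regulated gene of the endoplasmic reticulum, was 3.01-fold lower. Among adipocyte and lipid storage genes, whose median of 0.08 lay inside the random range, the fatty acid desaturase gene Scd was 2.47-fold lower and the brown fat lipid droplet gene Cidea was 1.78-fold higher. Pparg, the adipocyte regulator, was at 8.25 and 8.27. Glycolysis and glucose uptake genes had a median of 0.40 against a random range of -0.09 to 0.18. Of 27 compared members, 4 were at least 2-fold higher and 0 at least 2-fold lower. Slc16a3, a lactate exporter, was 11.8-fold higher and Hk2, a hexokinase, 2.38-fold higher, while Ldhb, a lactate dehydrogenase subunit, was 1.98-fold lower. In the hypoxia response list (median 0.35, random range -0.12 to 0.27, with the mean of 0.23 inside the range for means), the prolyl hydroxylase gene Egln3 was at least 3.23-fold higher and the carbonic anhydrase gene Car9 was 4.58-fold lower. None of the 45 respiratory chain genes was 2-fold apart, and their median of 0.08 lay inside the random range.

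Antioxidant and oxidant enzyme genes had a median of 0.25 against a random range of -0.06 to 0.16, with 7 of 35 compared members at least 2-fold higher and 1 at least 2-fold lower. The metallothionein genes Mt2A and Mt1a (9.08-fold) were the highest, and their similar sequences can share signal. The lower member was Nox4, an oxidase that makes hydrogen peroxide (3.65-fold lower). Txnip, which is induced by glucose in many cells, was 1.43-fold higher. Genes of the unfolded protein and integrated stress response had a median of -0.20 against a random range of -0.08 to 0.19, and 3 of 26 were at least 2-fold lower, among them the stress-induced nuclear protein gene Nupr1 (7.43-fold) and Atf5 (2.25-fold). Apoptosis regulator genes lay inside their random range with a median of 0.10 and a mean of -0.089. In that list the inflammatory caspase gene Casp4 was 4.46-fold lower and the survival gene Bcl2 4.11-fold lower, while the death-promoting gene Bcl2l11 was 2.27-fold higher. Heat shock protein genes lay inside their random range with a median of -0.04 and a mean of 0.15, with Hspb8 7.12-fold higher.

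Growth factor and signalling lists held large differences in both directions. In the TGF-beta, activin and BMP list, 8 of 32 compared members were at least 2-fold higher and 2 at least 2-fold lower, with a median of 0.33 against a random range of -0.08 to 0.18. Fst, the activin and myostatin antagonist follistatin, was 7.78-fold higher (a log2 difference of 2.96), and Id2, an inhibitor of differentiation factors that responds to BMP, was 6.92-fold higher. Tgfb2 was 2.30-fold lower and Bmp6 2.04-fold lower, Tgfb1 was 1.69-fold higher, and Bmp4 was under the floor in both arrays (7.61 and 7.28). With no filter on dim genes the median of this list was 0.049, inside the random range. In the Notch and Wnt list (median -0.34, random range -0.09 to 0.23, and -0.17 with no filter on dim genes), the Wnt antagonist gene Sfrp4 was 4.52-fold lower and the Notch ligand gene Jag1 4.03-fold lower, while Wnt4 was 4.48-fold and Wnt5a 2.89-fold higher. Among angiogenic factor genes (median 0.28, random range -0.11 to 0.22, and 0.10 and inside it with no filter on dim genes), Fgf7 and the EGF receptor ligand gene Ereg (9.11-fold) were higher, and Fgf1 (5.27-fold) and Pdgfd (2.86-fold) were lower. Vegfa was at 11.27 and 11.48.

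Among insulin and IGF pathway genes, whose median was 0.04, Pappa, a protease of IGF-binding proteins, was 7.37-fold higher and the insulin receptor substrate gene Irs2 was 2.28-fold lower. Of the neurotrophin and glial factor genes (median -0.03, mean 0.026), Clcf1, a cytokine of the interleukin-6 family, was 2.15-fold higher, and Cntf, ciliary neurotrophic factor, was 3.19-fold lower. In the list of stem cell and mesenchymal surface markers (median -0.06, mean 0.20), Ly6e was 9.04-fold higher and Mcam, a surface adhesion molecule of perivascular cells, 2.88-fold lower. Pou5f1, a pluripotency factor, was below the background level in both arrays (6.12 and 5.52). Imprinted growth genes had a median of 0.11 and a mean of -0.067 over 5 compared members, with Snrpn 1.60-fold lower. Hox position genes had a median of -0.16, inside the random range but below it with the loess trend removed (-0.19) and against unmatched random lists, with Hoxd13 3.69-fold lower and Hoxa10 2.73-fold and Hoxa5 2.18-fold higher.

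Most markers of other cell types that the cultures could hold were under the floor for comparison, the fibroblast set excepted. Many still lay above the background level in at least 1 array: 8 of 13 endothelial, 6 of 9 pericyte, 7 of 10 tendon and 16 of 19 fibroblast markers. So did 9 of 12 epithelial and 10 of 12 Schwann cell and glial markers, but only 2 of 7 red blood cell markers. Of all 18489 genes, 12974 lay above that level in the early array alone. Such shares therefore do not show these cell types to be present, and the cell types are not shown to be absent either. Of 13 measured endothelial markers, 2 could be compared: Flt1, a VEGF receptor, was 9.40-fold lower, and Egfl7, chosen after its values were seen, was at 9.18 and 9.26. Of 9 pericyte markers, 4 could be compared. Cspg4, the proteoglycan NG2, was 5.22-fold lower and Pdgfrb 1.52-fold lower, while the aminopeptidase gene Anpep was 2.92-fold higher. Of 10 tendon markers 3 could be compared, and Thbs4 and Scx were 2.67-fold and 1.72-fold lower. The set of fibro-adipogenic progenitor and fibroblast markers had a median of 0.12 over 11 compared members, inside its random range, with 3 of them at least 2-fold higher. The mean (0.66) and the median with the 75th percentile filter (0.38) lay above their ranges. Penk, the enkephalin precursor, was 9.84-fold higher and Fap, a fibroblast surface protease, at least 2.58-fold higher. Of the epithelial and mesothelial set, 2 of 12 markers could be compared, and the keratin gene Krt7 was 6.35-fold higher. Of 12 Schwann cell and glial markers 2 could be compared, with a median of -0.11, and of 7 red blood cell markers 1, at a difference of -0.31.

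Among the comparison lists, 22 reference genes had a median of 0.09, inside their random range. Tfrc, the transferrin receptor, was the 1 member at least 2-fold apart, 2.94-fold higher. The 51 ribosomal protein genes had a median of -0.08, just below their random range of -0.06 to 0.11, and 0 of them were 2-fold apart. Their mean of -0.074 lay inside the range for means. The lowest, Rpl30, was 1.65-fold lower on the mean of 3 probe sets, which gave -0.17, -1.83 and -0.16. Both cultures are described with media of 5.6 mM or 22 mM glucose, and the labels do not say which array had which, so a difference between the arrays can hold a difference in medium glucose. With 1 array per group, the difference between early and late diabetes cannot be told apart from that between any 2 cultures.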

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

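Probe sets with no gene symbol were left out of the comparison, and some of them carried large differences. Of 2311 such probe sets bright enough to be compared, 107 were at least 2-fold apart (4.63%), 81 higher and 26 lower in the late array. The largest difference upward was 4.33 on the log2 scale and the largest downward -3.33. These probe sets stand out because they hold signal that no comparison above uses, and what they measure is not given in the sources used here. Of 10833 named probe sets bright enough to be compared, 911 were at least 2-fold apart (8.41%), a larger share than among those with no symbol. How many of the probe sets with no symbol are control probe sets of the array is not known here, so the shares are not on a like basis.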

How the results depend on the processing

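The background filter and the removal of genes held by several lists were chosen after the result was seen. The genes at least 2-fold apart, 569 higher and 303 lower, came to 1177 and 631 at 1.5-fold, 237 and 129 at 3-fold, and 280 and 177 with the 75th percentile filter, which follows from what these settings count. Under the other alternatives the counts stayed within 1.5 times, from 503 to 663 higher and from 285 to 344 lower. The share of calls that were higher was 65.3% as reported and 59.4% after quantile normalization, its lowest value. With no filter the correlation of the arrays was 0.97 and that of 2 probe sets of one gene 0.61. Of the 19 lists outside their random range, 12 stayed outside in the same direction under all alternatives run: cell cycle, cytokine, matrix protease, glycolysis, antioxidant, cholesterol synthesis, skeletal muscle contractile, collagen and matrix, bone and cartilage, senescence, unfolded protein, and Notch and Wnt genes. The sizes of some of these medians moved by more than 1.5 times. With no filter and with the background filter, cytokine, chemokine and NF-kB genes came to 0.60 and 0.97, skeletal muscle contractile and differentiation genes to -0.21 and -0.27, bone and cartilage genes to -0.26 and -0.26, and Notch and Wnt pathway genes to -0.17 and -0.17. With the 75th percentile filter the muscle list came to -1.98 and the Notch and Wnt list to -0.59. By the mean the muscle list came to -1.28, bone and cartilage to -0.82, antioxidant to 0.52 and unfolded protein to -0.36. The other 7 lay inside under at least 1 alternative. With no filter these were the TGF-beta, activin and BMP pathway genes (median 0.049, also with the background filter, 0.049), angiogenic factor (0.10) and nitric oxide (-0.16) lists. With the 75th percentile filter they were the myogenic regulator (-0.21), hypoxia (0.20) and nitric oxide (-0.20) lists, and by the mean the smooth muscle (-0.12), hypoxia (0.23), nitric oxide (-0.023) and ribosomal protein (-0.074) lists. In turn, 3 lists inside their range as reported lay outside elsewhere. The fibroblast set did so with the 75th percentile filter (0.38) and by the mean (0.66), and Hox genes with the loess trend removed (-0.19) and against unmatched random lists (-0.16). The interferon-stimulated and antigen presentation genes lay below their range with the 75th percentile filter (-1.497), quantile normalization (-0.32), median centring (-0.29), the brightest probe set (-0.24), the background filter (-0.17), unmatched lists (-0.12) and without genes of other lists (-0.23). Which filter is right for these lists was not tested, and the cause was not tested. Scaling moved the median difference of all genes by 0.03 (loess), 0.01 (quantile) and -0.07 (centring). These scalings moved a gene by at most 0.14, too little to turn a 2-fold difference, so they say little about the stability of single genes. The brightest probe set moved Xirp1 to 0.92, Ifit1 to -0.93 and Rpl30 to -0.16. The other deposited table was not run as an alternative, since its values are identical. No paired analysis was possible because each group has 1 array, and no array could be left out for the same reason.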

Other observations

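The tests of white blood cells, of fewer muscle cells and of medium glucose were chosen after the result was seen. Some genes ranked 13th to 40th by difference in each direction are given here, chosen after their values were seen and standing for no group. Higher in the late array were Bdkrb1, the bradykinin B1 receptor (at least 7.69-fold), Ccr1, a chemokine receptor (at least 4.48-fold), Cd93 (9.26-fold), Slc11a1, a metal transporter of phagocytes (7.81-fold), and Ccl7, a monocyte chemokine (9.24-fold). Pygl, a glycogen phosphorylase, was 12.9-fold higher, and Lrrc32, which holds latent TGF-beta at the cell surface, 8.42-fold higher. Slc5a7, a choline transporter of nerve cells, was at least 6.68-fold higher.

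Among the lower genes of the same ranks, the integrin genes Itga4 and Itga11 were 10.8-fold and 6.18-fold lower in the late array. Slit3, a guidance factor, differed by -3.09 on the log2 scale, and Aspn, asporin, was 6.40-fold lower and Cdh13, T-cadherin, 6.42-fold lower. Bmper, a BMP-binding protein, was 6.85-fold lower.

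For the higher cytokine genes, the smallest list median after quantile normalization, median centring or loess was 1.52, still outside the random range. The random lists were drawn from the same rescaled genes and matched on brightness, so this placement was nearly fixed in advance. It cannot decide on scaling between arrays or a trend with brightness. These corrections moved a gene by at most 0.14, beside the list median of 1.58. That size counts against an array-wide shift or smooth trend left in the deposited values, not against other technical differences. White blood cells of many kinds in the late culture would raise most of their markers. The median difference of 20 markers was -0.025 (bootstrap 95% interval over the markers -0.11 to 0.12). The cytokine list median was 1.58 over compared genes and 0.60 over all measured members, the like basis. Only 6 of the 20 markers lay above the background level in the late array, so the markers' median is set mostly by dim ones. It cannot exclude a few white blood cells or cells of 1 kind. Ptprc, Lyz2 (6.21 in both arrays) and Tyrobp (6.65 and 6.57), chosen after their values were seen, lay below the background level in both arrays. Of all 20 markers, 40% were higher in the late array. The 6 above the background level there were Cd68, Cd14, Csf1r, Cd53, C1qb and Cd79b. Cd68, Cd14, Csf1r (0.90 on the log2 scale) and Cd53 (6.29 and 7.65) were higher in the late array, the last 2 also chosen in this way. A few such cells or the stem cells themselves may carry these. A few white blood cells in the late culture stay open. The stage of diabetes, a stimulus in 1 culture and chance between cultures stay open and untested.

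For the lower muscle contractile genes, scaling left a list median of -0.55 where it was smallest in size, outside the random range. The limit given for scaling of the cytokine genes holds here too. Fewer differentiated muscle cells in the late culture would need such cells, with their abundant RNAs, in the early one. The median early value of all 41 measured contractile genes was log2 7.19 (upper end of the bootstrap 95% interval 7.41), under the floor of 8.03. The 4 members at least 2-fold lower had an early median of 11.14, but a bright early value follows from how they were selected. Neb (6.62), Mylpf (6.79) and Tnnt3 (7.38), chosen after their values were seen, lay far below Casq2 (11.84) in the early array. Neb and Mylpf were there below the background level, and levels of different probe sets do not measure relative amounts of RNA. These levels cannot decide on a loss of differentiated muscle cells, since a small share of such cells could leave most of the list under that floor. The early level was taken up after values were seen. It replaced a first test on the SD of the differences, which had no bound that could exclude such a loss. The 9 contractile genes above the floor in the early array differed by anything from -4.46 to 0.34, with an SD of 1.84, and 4 of them were within 1.5-fold lower or higher. Among those 4, and chosen after their values were seen, were Acta1 (10.57 and 10.68), Ckm (9.09 and 8.88) and Jph2 (10.44 and 10.35). The 9 genes were thus not lower by a like amount, which a loss of cells that alone make all 9 would give. A loss of differentiated muscle cells as part of the cause stays open. Cells that use only part of the muscle genes, the stage of diabetes and chance between cultures stay open and untested.

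For the higher cell cycle genes, the smallest list median after another scaling was 1.23, with the limit given for scaling of the cytokine genes. A difference in medium glucose may lie between the arrays, since the labels give 2 levels. Arrdc4, chosen after the result was seen and like Txnip responsive to glucose in many cells, was 1.30 higher on the log2 scale and Txnip 0.52 higher. Both are more than the probe set SD of 0.22, but that SD covers probe error only. The differences of all compared genes had an SD of 0.64, which is more than the difference of Txnip. Both genes also respond to other signals, and no array of known glucose was compared, so this cannot be told apart from the stage of diabetes or from how dense the cells were at harvest.

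Whether genes at least 2-fold apart lie next to each other on the chromosomes was asked of 9318 compared genes that could be placed by order. There were 58 adjacent pairs in the same direction, where shuffled calls gave a median of 40, a central 95% of 29 to 53 and a highest count of 59, and 1 of 1000 shuffles gave as many. Of the 58 pairs, 13 had symbols that share a stem, with Mt1a and Mt2A, Casp4 and Casp12, and Fads1 and Fads2 as examples picked after the pairs were seen. A shared stem is only a rough mark of a gene family. It takes in Mir145 and Mir143, whose stem stands for any microRNA gene. The other 45 pairs lie within the central range of the shuffles, which were not cleared of pairs that share a stem. Local duplicated gene families may therefore account for the excess, as far as the stem marks them. The bound set before the result was seen, more pairs than any shuffle, was not met, and the hypothesis that neighbours differ together beyond such families stays open. The lower neighbours Ogn, Omd and Aspn, also picked out afterwards, are 3 small leucine-rich proteoglycan genes in a row. Their symbols share no stem, so their pairs are among the other 45.

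The scaling test was also run on the lower cholesterol synthesis genes, whose smallest list median in size was -1.09, outside the random range. The limit given for scaling of the cytokine genes holds here too.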
